A study of Homo sapiens with 12 samples.

How the data were processed

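RNA-seq of 12 libraries was used, 3 each of wild-type and ASAP2 knockout cells of the human pancreatic ductal adenocarcinoma lines Panc1 and MiaPaCa2. Per the labels' protocols, total RNA was extracted with ISOGEN II and the libraries were sequenced on a BGISEQ-500. Per the series design text and the submitters' processing notes, reads were trimmed for adaptors, reads of low quality or low complexity were removed, the rest were aligned to hg19 with its UCSC gene annotation by TopHat2 2.0.14, and FPKM was calculated with STAR 2.5.2a. The deposited values are FPKM per gene symbol, 1 file per library, with 3 decimals. Library preparation, strandedness, read length, read number, the treatment of reads that map to several places, the way the knockout was made and the number of clones are not given in the sources used here. Since the use of strand in counting is not stated, reads of a gene and of an overlapping gene on the other strand cannot be told apart.

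No symbol occurred more than once in a library. In all 22650 symbols occurred in any library and 15286 in each of the 12, between 5 and 11 genes per library were listed at 0, and a gene absent from a library was taken as 0. FPKM summed to between 360765 and 392610 per library, with 362717 ± 2267 (SD, n = 3) in Panc1 wild-type, 382256 ± 2096 in Panc1 knockout, 387368 ± 4583 in MiaPaCa2 wild-type and 387543 ± 6725 in MiaPaCa2 knockout libraries. The 10 genes with the highest values held 7.3 to 9.5% of the sum. Read depth is unknown: a search for the FPKM steps of single reads over a range of depths, in 182 to 220 short RNA genes per library, left a mean distance to the nearest whole number of 0.23 to 0.25, where values without steps give 0.25. A test on read counts was therefore not possible, and no interval from counting error is given.

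The fit was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with 1 mean for each of the 4 groups over all 12 libraries (8 residual degrees of freedom), empirical Bayes moderation with a mean-variance trend, two-sided tests, and Benjamini-Hochberg adjustment over the 13340 genes with a mean of at least 1 FPKM over the 6 libraries of a line in at least 1 line. A gene was called at an adjusted p below 0.05. The contrasts were knockout against wild-type in each line, the difference between these, and wild-type Panc1 against wild-type MiaPaCa2, the last counted also at 2-fold. Overlaps between the lines were set beside the product of the calls divided by the genes tested, and the lines share no libraries. The 36 gene lists were written from general knowledge and tested with limma's camera at its preset correlation of 0.01 where at least 5 members were tested, with Benjamini-Hochberg adjustment over all lists and both lines. The difference between lines was tested likewise over 32 lists.

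The genes named in the text follow a rule. It takes ASAP2; in each line the 8 largest increases and 8 largest decreases among called genes without overlap between the groups and with a mean of at least 5 FPKM in the higher group; in each line and list the 3 called members with the largest change, no overlap and a mean of at least 1 FPKM; the 6 genes highest and the 6 lowest in both lines by the smaller change; the 6 genes with the largest difference and opposite calls; and the 6 largest differences each way between the wild-type lines. Of the list members that this gives, those of the lists that passed are named for the most part, and a selection of the others; some genes are not reported here. For shared and opposite changes the rule also asks for a mean of at least 5 FPKM in the higher group of each line. For the wild-type lines it asks for this mean in the higher line. ATF4, STAT2, IRF9, ASAP1 and CORO1A are list members outside the rule, named after their values were seen. The groups, the test, the lists, this rule and the alternatives were set before the data were examined, except those said to be chosen after.

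The alternatives set in advance were another pseudocount (0.1), no filter and a filter of 5 FPKM, rescaling of each library to the same sum (TPM scale) or by the median ratio, quantile normalization, limma without the trend, array weights, each line fitted alone, the replicate number as a block, genes listed in all 12 libraries alone, each library left out in turn, camera with an estimated correlation, and fry. With a library left out, a group of 2 is assumed to vary like the others. The other handling of duplicate symbols changed nothing, since there were none, and the count test could not be run. Chosen after the data were seen were a correction of each library for GC content and gene length by loess (span 0.3, degree 1) on 12441 genes, 93.3% of those tested, a fit without the genes in the first 90 Mb of chromosome 2, and a fit without chromosomes 2 and 7. Positions, lengths and GC content came from GENCODE release 44 mapped to GRCh37 (hg19), where 19799 symbols had a single position. Runs along chromosomes were compared as medians of as many neighbouring genes, over genes with a mean of at least 2 FPKM.

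The procedure was tested on simulated data, with 50 of 13340 genes changed per size: changes of 1.25, 1.5, 2 and 4-fold were recovered in 50, 84, 98 and 100% in the Panc1 comparison and in 38, 88, 98 and 96% in the MiaPaCa2 comparison, and 0.05% and 0.04% of unchanged genes were called. The simulated noise was independent between genes and libraries, and few genes were changed. These rates therefore do not cover differences shared by many genes of a culture or library. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Groups of 3 libraries against 3 allow no exact p below 0.1 for a single value, and splits of such libraries number 10.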

Results

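RNA from a pair of human pancreatic ductal adenocarcinoma cell lines, Panc1 and MiaPaCa2, was sequenced with and without a knockout of ASAP2, a GTPase-activating protein for Arf proteins that acts in membrane trafficking and at focal adhesions. The 4 groups, wild-type and knockout cells of each line, had 3 libraries each, which makes 12 libraries. The values are FPKM per gene as the submitters deposited them. Between 17958 and 19105 genes were listed per library, and 11842 to 12500 of them reached 1 FPKM. Read depth is unknown, because the files hold no counts and whole reads could not be recovered from the FPKM values. Libraries of the same group correlated across genes at r = 0.9936 to 0.9971, those of the other genotype in the same line at 0.9679 to 0.9893, and those of the other line at 0.7863 to 0.8107. Levels below are the mean ± SD of 3 libraries, and fold changes are on the scale of log2(FPKM + 1), which understates the change of low genes; a gene that rose or fell by a given amount did so on that scale. The test for genes was limma with Benjamini-Hochberg adjusted p-values over 13340 genes. Whether the 3 libraries of a group came from separate cultures or clones is not given in the sources used here, so p-values measure only the spread between these libraries.

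ASAP2 itself was the first gene to look at, since its level checks the labels. In Panc1 its mRNA fell from 36.9 ± 2.04 to 13.8 ± 0.978 FPKM (log2 change -1.36, SE 0.07, adjusted p = 1.5e-08). The single libraries held 38.6, 37.5 and 34.6 FPKM in wild-type cells and 14.2, 14.5 and 12.7 FPKM in knockout cells. In MiaPaCa2 the level was 13.5 ± 0.320 FPKM in wild-type and 12.3 ± 1.29 FPKM in knockout libraries (log2 change -0.13, SE 0.07, adjusted p = 0.197), so no difference was found. The wild-type libraries of MiaPaCa2 held 13.2, 13.6 and 13.8 FPKM and the knockout libraries 12.01, 13.8 and 11.3 FPKM. A frameshift made by genome editing need not lower the amount of mRNA, and the kind of edit is not given in the sources used here. The MiaPaCa2 labels are neither contradicted nor checked by this gene. With array weights the MiaPaCa2 difference was -0.17 (adjusted p = 0.0153), after a GC and length correction it was -0.18 and without knockout replicate 2 it was -0.20, and these passed as well. Over all alternatives its adjusted p ran from 0.0153 to 0.523. The change in Panc1 minus that in MiaPaCa2 was -1.23 (adjusted p = 1.3e-06). The gene lies on chromosome 2, 9346894 to 9545812 in GRCh37 (hg19), on the forward strand and is protein coding.

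**Figure D1:**
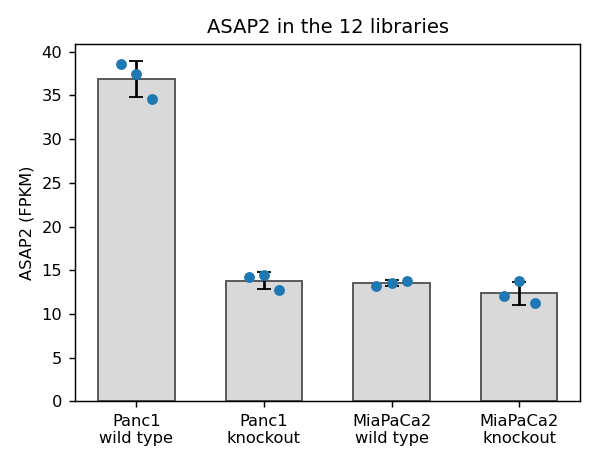
ASAP2 level in FPKM in each library (points), with bars for the mean and error bars for the SD of 3 libraries in each of the 4 groups. The Panc1 knockout mean is 13.8 FPKM against 36.9 FPKM in wild-type cells, while the MiaPaCa2 groups overlap.

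Genes around ASAP2 on the short arm of chromosome 2 were also lower in the knockout libraries, a stretch that was looked for only after the values had been seen. In Panc1, the 52 tested genes of the first 25 Mb had a median log2 change of -0.60 relative to that of the other genes, and 50 of them lay below it (96.2%). The lowest run of as many neighbouring genes on other chromosomes stood at -0.54, so 0 of 8619 such runs were as low. In MiaPaCa2 the stretch was taken up to 85 Mb, though few tested genes lie between 75 and 85 Mb. Its 249 genes had a median of -0.38 relative to the rest, and 234 of them lay below it (94%). The lowest of 4184 runs on other chromosomes stood at -0.18. The window from 70 to 75 Mb stood at -0.441 and that from 85 to 90 Mb at -0.079. The first 25 Mb alone stood at -0.32 in MiaPaCa2, where 14 of 8189 runs on other chromosomes were as low. The whole of chromosome 2 stood at -0.21 there, with 81.1% of 650 genes below the rest, and most windows of the long arm lay below 0 as well. The windows were read after the GC and length correction. The boundaries of both stretches were set from the data. ASAP2 changed more than its neighbours in Panc1, where it ranked 2 from the lowest of 52 genes, and less than most in MiaPaCa2, where it ranked 204 of 249. These ranks were taken after the GC and length correction, unlike the medians of the stretches above. Genes named below that lie in these stretches lie where this shift was seen: RRM2, ID2 and HPCAL1 in both lines, and CAD, CENPA, PNO1, SFXN5 and ACTG2 in MiaPaCa2 alone. Chromosome 7 was lower in the Panc1 knockout libraries as well, with a median of -0.297 relative to the other genes over 477 genes, and IGFBP3, AGR2, ANLN and EGFR lie on it. Chromosome 6 was higher in these libraries, with a median of 0.173 over 482 genes, and HLA-B, HLA-C, DSP, CDKN1A, CCN2 and HIST1H1C lie on it. DNA was not measured.

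**Figure D2:**
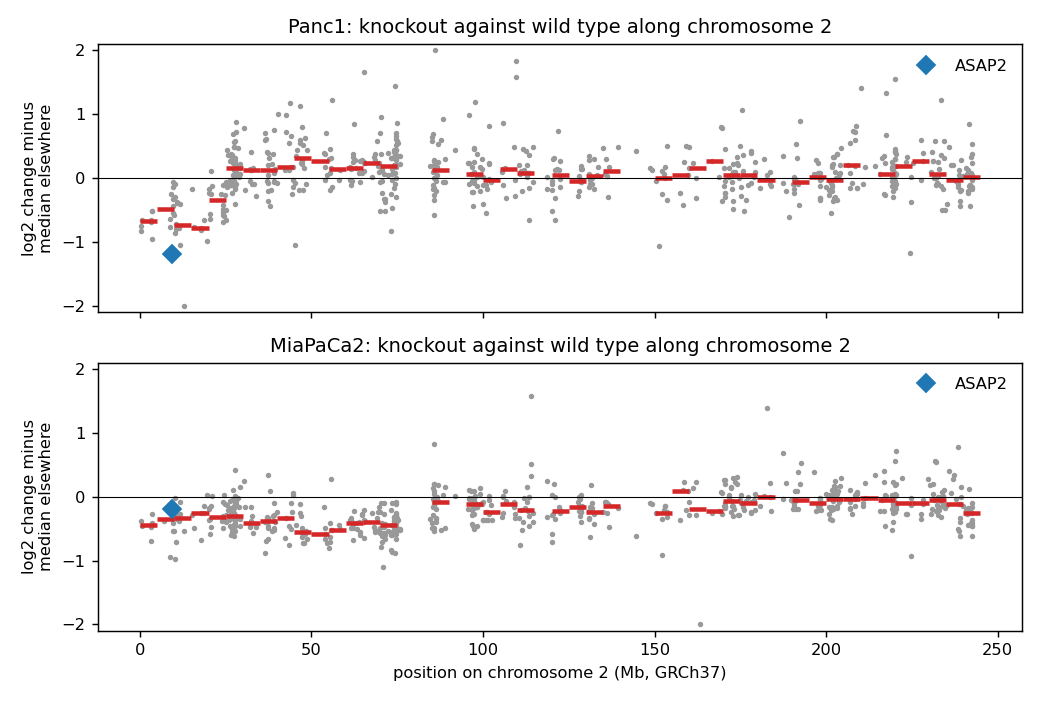
Log2 change after the GC and length correction along chromosome 2 (position in Mb, GRCh37), minus the median of the genes elsewhere, in each line. Genes had a mean of at least 2 FPKM in the line, and changes beyond 2 are drawn at 2 or -2. Red bars are medians of 5-Mb windows and the blue diamond is ASAP2. In Panc1 the medians lie below 0 up to about 25 Mb and near or above 0 beyond. In MiaPaCa2 they lie below 0 up to 75 Mb, and none is drawn from 75 to 85 Mb, where windows held fewer than 5 genes. Beyond 85 Mb they lie below 0 in most windows, for the most part nearer to 0.

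The single genes that gained most in Panc1 were of several kinds. The gene that gained most was FHL1, a LIM-domain protein of actin-rich structures, which rose from 3.44 ± 0.499 to 57.3 ± 1.68 FPKM (log2 change 3.72, SE 0.10, adjusted p = 4.9e-11) and lies on chromosome X, 135228861 to 135293518. COL5A1, a chain of collagen V, rose from 6.06 ± 0.279 to 82.9 ± 5.67 FPKM (log2 change 3.57) on chromosome 9, 137533649 to 137736689. DSP, the desmosome protein desmoplakin, went from near 0, at 0.266 ± 0.0416 FPKM, to 7.47 ± 0.266 FPKM (log2 change 2.74). SERINC2, of a family of lipid scramblases, rose from 11.3 ± 0.387 to 85.8 ± 8.41 FPKM (log2 change 2.82). CHAC1, which breaks down glutathione and is a target of ATF4, the transcription factor of the integrated stress response, rose from 3.43 ± 0.404 to 25.7 ± 2.12 FPKM (log2 change 2.59, SE 0.08, adjusted p = 2.6e-10). ST3GAL5, a sialyltransferase that makes gangliosides, rose from 2.54 ± 0.241 to 18.2 ± 1.38 FPKM, and the long noncoding RNA LOC101448202 from 0.522 ± 0.0155 to 7.26 ± 0.586 FPKM. TUBB2B, a beta-tubulin of neurons, read from 3.98 ± 0.330 to 36.4 ± 2.34 FPKM, but it has a near-identical neighbour and its level is uncertain.

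The genes that lost most in Panc1 included secreted factors, a growth factor receptor and a marker of secretory epithelium. CCL2, a chemokine that draws monocytes, fell from 18.7 ± 0.860 to 1.58 ± 0.783 FPKM (log2 change -2.98, SE 0.16, adjusted p = 1.6e-08) and lies on chromosome 17, 32582293 to 32584227. IGFBP3, which binds insulin-like growth factors and lies on the lower-reading chromosome 7, fell from 10.999 ± 0.515 to 1.14 ± 0.112 FPKM (log2 change -2.48, SE 0.06, adjusted p = 1.6e-11). PDGFRA, a receptor for platelet-derived growth factor, fell from 11.2 ± 0.439 to 1.52 ± 0.183 FPKM (log2 change -2.28). AGR2, a disulfide isomerase of secretory epithelium and a marker of the classical pancreatic cancer subtype, fell from 362 ± 9.57 to 68.1 ± 3.42 FPKM (log2 change -2.40). TBX2, a T-box repressor, fell from 10.7 ± 0.288 to 1.17 ± 0.146 FPKM, and the carboxylesterase gene CES1 from 6.28 ± 0.400 to 0.534 ± 0.146 FPKM. So did the endothelial lipase gene LIPG from 57.6 ± 0.110 to 11.8 ± 0.556 FPKM, and RFLNA, a regulator of filamin, from 10.9 ± 0.373 to 1.67 ± 0.0322 FPKM. The largest adjusted p of the 16 genes named in these paragraphs on single genes was 2.4e-06.

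Of 13340 genes tested in Panc1, 2910 were higher and 5556 lower in knockout libraries (limma, Benjamini-Hochberg adjusted p below 0.05), which is 63.5% of the genes. At least 2-fold changes were found for 196 genes upward and 168 downward. These counts were 377 and 403 with a pseudocount of 0.1, so their balance depends on it. With a filter of 5 FPKM 126 were higher, and 103 were lower with median-ratio scaling and 102 with the GC and length correction. The direction of the bulk depends on scaling: 65.6% of the called genes were lower in the values as deposited, 47.2% after rescaling by the median ratio (4327 higher and 3875 lower), and 52% after quantile normalization (3940 and 4263). It was 51.8% after a correction for GC content and length (3591 and 3863) and 73.7% on the TPM scale (2335 and 6553). Rescaling by the median ratio, quantile normalization and the GC and length correction centre the changes, so a near-even split follows from them. The all-gene median log2 change was -0.10 in the deposited values and 0.01 after rescaling by the median ratio. No overlap between the 3 wild-type and the 3 knockout values was seen in 70.1% of the genes, where chance alone gives 10%.

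Among the 36 gene lists fixed before the data were examined, 32 had enough tested members in a line, and in Panc1 9 passed upward and 2 downward with camera at its preset correlation. With an estimated correlation 0 did, and with fry 15 were higher and 12 lower. Without a filter 5 were higher and 5 lower, and with quantile normalization 5 and 4. In the stress response list 25 rose and 11 fell of 40 tested (median log2 change 0.61, 0.72 relative to all genes, camera adjusted p = 6.7e-06, and adjusted p = 0.401 with an estimated correlation). Besides CHAC1 the rising genes included SESN2, a stress-induced inhibitor of growth signalling, at 1.94, the pseudokinase gene TRIB3 at 1.83, and ATF4 itself, which went from 110.1 ± 0.578 to 243 ± 24.1 FPKM. Ribosomal protein genes moved together: 62 rose and 2 fell of 72 tested (median log2 change 0.36, 0.46 relative to all genes, camera adjusted p = 8.5e-20, and adjusted p = 0.392 with an estimated correlation). They included RPL13 at 0.73 and RPS18 at 0.69, though these genes have many processed copies and single levels are uncertain. Of the focal adhesion and integrin genes, 19 rose and 9 fell of 36 tested (median log2 change 0.21, 0.31 relative to all genes, camera adjusted p = 4.2e-04, and adjusted p = 0.0535 with an estimated correlation). They included ITGB4 (log2 change 1.36, adjusted p = 5.0e-07), the integrin of hemidesmosomes, the actin crosslinker ACTN1 (log2 change 1.04, adjusted p = 2.4e-09) and the vitronectin-binding integrin ITGB3 (log2 change 0.99, adjusted p = 1.9e-07). For the AP-1 and immediate early genes, 14 rose and 3 fell of 21 tested (median log2 change 0.26, 0.36 relative to all genes, camera adjusted p = 4.9e-04, and adjusted p = 0.392 with an estimated correlation). ATF3, induced by stress, rose by 0.93 and JUND, an AP-1 subunit, by 0.88, while the growth-factor-induced EGR1 fell by 0.94, and the list did not pass without a filter.

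The matrix list had a median near 0, 0.04 as deposited and -0.02 on the TPM scale, with 11 higher and 5 lower of 28 genes (0.14 relative to all genes, camera adjusted p = 0.0119, and adjusted p = 0.338 with an estimated correlation). Without Panc1 knockout replicate 1 its median was 0.026, and it did not pass without a filter, with quantile normalization or with the GC and length correction. The list held COL5A1, COL1A1, the main collagen of stroma, which rose from 89.3 ± 2.56 to 314 ± 46.5 FPKM, and the protease inhibitor TIMP2, which rose from 26.2 ± 1.64 to 61.0 ± 2.63 FPKM. TGF-beta targets passed with 8 higher and 2 lower of 21 (median log2 change 0.11, 0.21 relative to all genes, camera adjusted p = 0.0260, and adjusted p = 0.415 with an estimated correlation). Without Panc1 knockout replicate 3 their median was 0.067, and they did not pass without a filter or with the GC and length correction. The feedback inhibitor PMEPA1 rose by 1.15, while the helix-loop-helix gene ID2, in the lower stretch of chromosome 2, fell by 0.79. Of the antigen presentation genes, 7 rose and 3 fell of 16 tested (median log2 change 0.09, 0.19 relative to all genes, camera adjusted p = 0.0308, and adjusted p = 0.392 with an estimated correlation). HLA-C and HLA-B read 1.23 and 1.16, each uncertain because of near-identical copies. The list did not pass with a filter of 5 FPKM or quantile normalization. Among actin cytoskeleton genes, 22 rose and 15 fell of 55 tested (median log2 change 0.07, 0.18 relative to all genes, camera adjusted p = 0.0333, and adjusted p = 0.209 with an estimated correlation). They did not pass without a filter, with quantile normalization or with the GC and length correction. The myosin light chain gene MYL9 rose from 80.4 ± 3.87 to 323 ± 22.0 FPKM. For the YAP and TAZ targets, 13 rose and 7 fell of 26 tested (median log2 change 0.13, 0.23 relative to all genes, camera adjusted p = 0.0381, and adjusted p = 0.524 with an estimated correlation). Their median was 0.086 without Panc1 wild-type replicate 2, and they did not pass without knockout replicate 1. Nor did they without a filter, with a filter of 5 FPKM, with quantile normalization, with the replicate block or without the first 90 Mb of chromosome 2. The matricellular CCN2 rose by 1.92 and the kinase gene NUAK2 by 1.89, against IGFBP3 at -2.48.

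Cell division genes were lower in Panc1. Of the mitosis genes, 1 rose and 48 fell of 52 tested (median log2 change -0.61, -0.51 relative to all genes, camera adjusted p = 3.8e-09, and adjusted p = 0.338 with an estimated correlation). The median was -0.44 after the GC and length correction. The hyaluronan receptor and spindle protein HMMR fell by 1.23, the condensin gene SMC4 by 1.07 and the cytokinesis gene ANLN, on chromosome 7, by 1.03. Of the replication and E2F target genes, 1 rose and 37 fell of 49 tested (median log2 change -0.36, -0.26 relative to all genes, camera adjusted p = 2.8e-04, and adjusted p = 0.634 with an estimated correlation). The ribonucleotide reductase gene RRM2 in the lower stretch of chromosome 2 fell by 1.13 and the cyclin gene CCNE2 by 0.92, and the cohesion factor DSCC1 fell from 8.32 ± 0.737 to 3.66 ± 0.484 FPKM. Adjusted over the list alone, the counts of members in Panc1 were the same as over all genes except that 38 E2F targets, 11 p53 targets, 8 NF-kB genes and 16 actin genes were lower, and 11 hypoxia genes were higher and 8 lower.

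**Figure D3:**
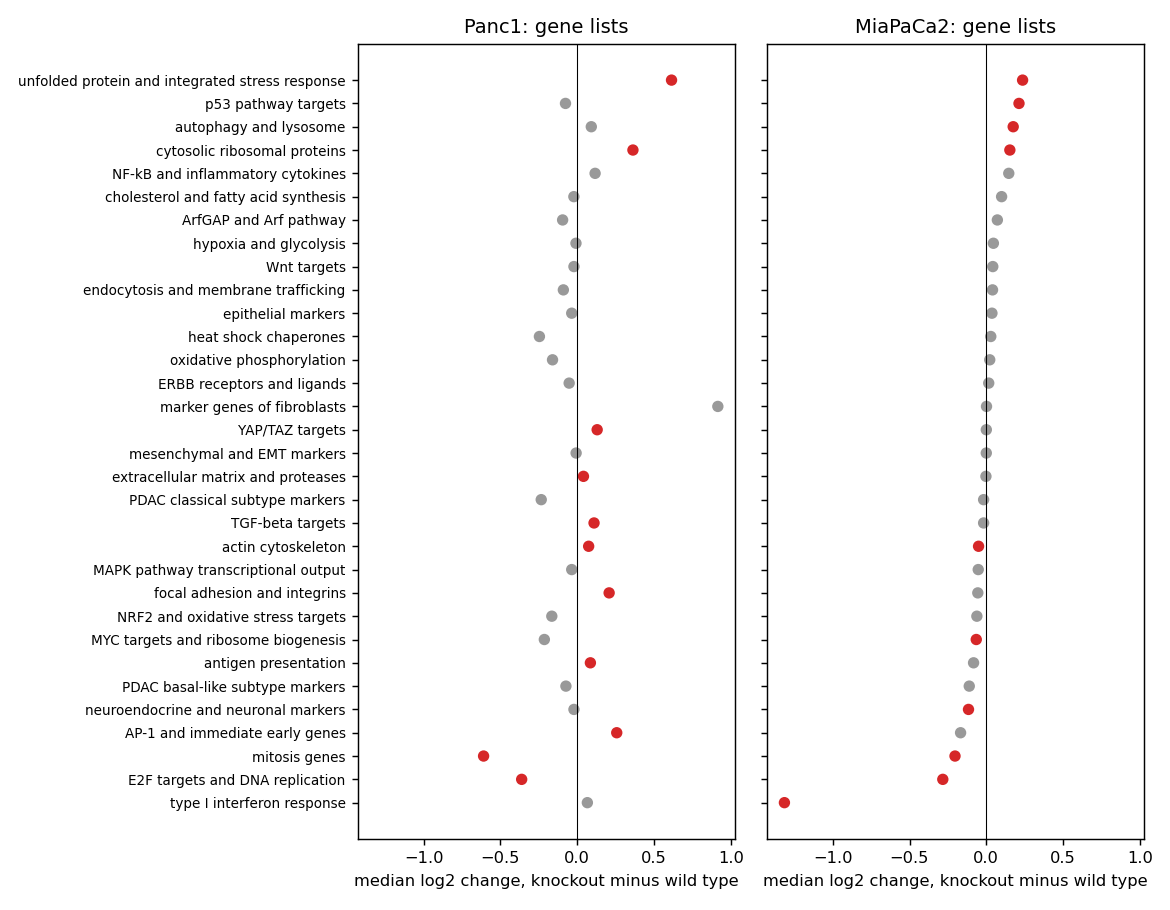
Median log2 change of each tested gene list in knockout against wild-type cells of each line, on a shared axis, with red points for a camera adjusted p below 0.05 and grey points otherwise. Interferon genes in MiaPaCa2 have the largest shift of the passing lists, at -1.31, and ribosomal protein genes lie above 0 in both lines.

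In MiaPaCa2 several of the genes that lost most are induced by interferon. OASL, an antiviral member of the oligoadenylate synthetase family, fell from 79.1 ± 6.37 to 8.79 ± 1.35 FPKM (log2 change -3.04, SE 0.10, adjusted p = 1.8e-09) and lies on chromosome 12, 121455566 to 121477049. ISG15, a ubiquitin-like modifier, fell from 184 ± 20.1 to 22.8 ± 5.80 FPKM (log2 change -2.98, SE 0.14, adjusted p = 2.6e-08) and lies on chromosome 1, 936518 to 949920. The antiviral IFIT3 and IFIT1, of which IFIT1 binds foreign RNA, fell from 47.7 ± 4.95 to 5.87 ± 1.31 FPKM and from 26.4 ± 3.10 to 4.21 ± 0.789 FPKM. IFIH1, the sensor of double-stranded RNA known as MDA5, fell from 7.53 ± 0.243 to 0.625 ± 0.0550 FPKM (log2 change -2.39, SE 0.05). RARRES3, a phospholipase induced by retinoids and interferon, fell from 19.0 ± 2.52 to 1.52 ± 0.174 FPKM, and the pattern-recognition gene PTX3 from 24.2 ± 3.52 to 2.44 ± 0.359 FPKM. The largest loss was that of ECSCR, a surface protein of endothelial cells, from 8.77 ± 1.19 to 0.109 ± 0.0392 FPKM (log2 change -3.13, SE 0.09, adjusted p = 6.4e-10).

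Genes that gained in MiaPaCa2 were of mixed kinds. LYZ, the secreted lysozyme, rose from 28.7 ± 8.33 to 122 ± 12.3 FPKM (log2 change 2.08, SE 0.24, adjusted p = 5.5e-05), and LAPTM5, a lysosomal membrane protein of blood cells, from 2.03 ± 0.436 to 16.9 ± 0.485 FPKM (log2 change 2.57). They carried the rise of the summed leukocyte markers, which were 60.5 ± 6.67 FPKM in wild-type and 159.9 ± 11.9 FPKM in knockout libraries. PRUNE2 rose from 0.456 ± 0.153 to 8.65 ± 0.785 FPKM (log2 change 2.73, SE 0.08, adjusted p = 6.4e-10), and the protocadherin gene PCDH1 from 1.91 ± 0.457 to 15.7 ± 3.90 FPKM. The steroid sulfatase gene STS rose from 1.78 ± 0.245 to 10.7 ± 2.49 FPKM, the Popeye-domain gene POPDC3 from 3.84 ± 0.526 to 18.3 ± 2.01 FPKM and the noncoding RNA LINC01444 from 1.13 ± 0.371 to 9.16 ± 0.903 FPKM. AKR1C1, an aldo-keto reductase, read from 13.6 ± 3.22 to 63.2 ± 8.11 FPKM, and is uncertain because close copies share its sequence. The largest adjusted p of the 16 genes in these paragraphs was 5.5e-05.

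Of 13340 genes tested in MiaPaCa2, 2373 were higher and 2172 lower in knockout libraries (limma, Benjamini-Hochberg adjusted p below 0.05), which is 34.1% of the genes. At least 2-fold changes were found for 51 genes upward and 48 downward. These counts were 131 and 100 with a pseudocount of 0.1 and 30 and 29 with a filter of 5 FPKM. The all-gene median log2 change was 0.01. No overlap between wild-type and knockout values was seen in 43.5% of the genes, where chance alone gives 10%.

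In MiaPaCa2 4 gene lists passed upward and 6 downward with camera, and 1 did with an estimated correlation. The count of downward lists was 3 without knockout replicate 2, with a filter of 5 FPKM, with quantile normalization, with array weights and without chromosomes 2 and 7. That 1 was the type I interferon response, where 0 rose and 26 fell of 34 tested (median log2 change -1.31, camera adjusted p = 8.5e-23, and adjusted p = 0.0119 with an estimated correlation). The signalling genes upstream changed little: STAT2 read 6.88 ± 0.146 and 6.90 ± 0.323 FPKM and IRF9 5.67 ± 0.976 and 6.23 ± 0.167 FPKM in wild-type and knockout libraries. The wild-type cells of MiaPaCa2 read far more of these genes than either Panc1 group: the median log2(FPKM + 1) of the list was 2.885 ± 0.124 in MiaPaCa2 wild-type, 1.933 ± 0.040 in MiaPaCa2 knockout, 1.429 ± 0.109 in Panc1 wild-type and 1.801 ± 0.015 in Panc1 knockout libraries. In Panc1, 13 of the 34 interferon genes rose and 8 fell (median 0.07, camera adjusted p = 0.0600), so the list as a whole did not pass there. It did with a pseudocount of 0.1, on the TPM scale and without MiaPaCa2 knockout replicate 1. The antigen presentation list had 3 higher and 6 lower of 16 in MiaPaCa2 (median -0.08, camera adjusted p = 0.108).

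**Figure D4:**
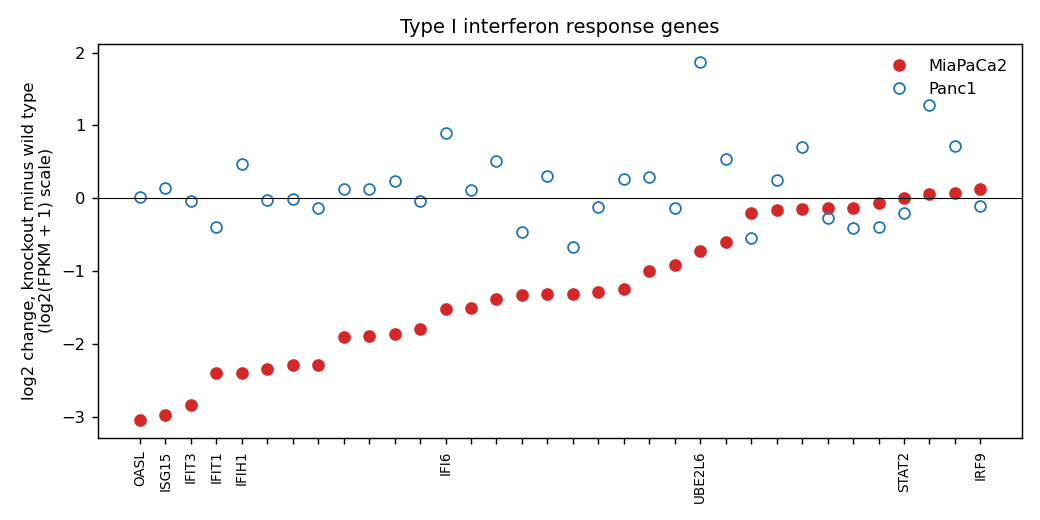
Log2 change in knockout against wild-type cells of the 34 tested members of the type I interferon list, with filled red points for MiaPaCa2 and open blue points for Panc1 and names for genes given in the text. In MiaPaCa2 26 members fell and none rose, while in Panc1 13 rose and 8 fell.

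The other lists that passed in MiaPaCa2 were of several kinds, and none of them passed with an estimated correlation. Of the E2F targets, 1 rose and 33 fell of 49 tested (median log2 change -0.28, camera adjusted p = 1.5e-08, and adjusted p = 0.514 with an estimated correlation). Without MiaPaCa2 knockout replicate 2 the median was -0.18. RRM2, on the short arm of chromosome 2, stood at -0.94, and GINS4, a part of the replicative helicase, went the other way at 0.86. Of the mitosis genes, 0 rose and 28 fell of 52 tested (median log2 change -0.20, camera adjusted p = 1.1e-07, and adjusted p = 0.392 with an estimated correlation). The kinesin gene KIF4A stood at -0.69, the checkpoint kinase BUB1 at -0.50 and the centromere histone CENPA at -0.48. Ribosomal protein genes had 35 higher and 2 lower of 72 (median log2 change 0.15, camera adjusted p = 1.9e-07, and adjusted p = 0.576 with an estimated correlation). In the stress response list 21 rose and 5 fell of 40 tested (median log2 change 0.24, camera adjusted p = 0.00118, and adjusted p = 0.514 with an estimated correlation). DDIT4, an inhibitor of mTOR signalling, rose from 25.9 ± 6.14 to 62.5 ± 12.6 FPKM, CHAC1 from 6.26 ± 0.697 to 12.7 ± 0.465 FPKM and the transcription factor gene CEBPB by 0.87. Of the autophagy and lysosome genes, 20 rose and 1 fell of 39 tested (median log2 change 0.18, camera adjusted p = 6.1e-05, and adjusted p = 0.392 with an estimated correlation). The autophagosome gene GABARAPL1, the saposin precursor PSAP and the hexosaminidase HEXA rose by 0.71, 0.69 and 0.62. In Panc1 14 of that list rose and 10 fell (median 0.09, camera adjusted p = 0.0612). It passed there with each line fitted alone and without MiaPaCa2 wild-type replicate 1.

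Of the p53 targets, 15 rose and 2 fell of 26 tested in MiaPaCa2 (median log2 change 0.21, camera adjusted p = 0.00192, and adjusted p = 0.338 with an estimated correlation). The AKT inhibitor PHLDA3, the stress cytokine GDF15 and the polyamine enzyme SAT1 rose by 1.66, 0.89 and 0.84. In Panc1 that list was mixed, 9 higher and 10 lower (median -0.08, camera adjusted p = 0.447), although SESN2, the cell-cycle inhibitor CDKN1A and GDF15 rose by 1.94, 1.41 and 1.37. MYC targets and ribosome biogenesis genes had 1 higher and 12 lower of 46 (median log2 change -0.07, camera adjusted p = 0.0137, and adjusted p = 0.623 with an estimated correlation). Of these genes 5 lie on the short arm of chromosome 2, among them the ribosome assembly factor PNO1 and the pyrimidine enzyme CAD, and the list did not pass without the genes of the first 90 Mb of that chromosome. Nor did it with a filter of 5 FPKM, quantile normalization or array weights, or without chromosomes 2 and 7. In Panc1 it had 6 higher and 25 lower (median -0.21, camera adjusted p = 0.166), and passed without a filter. Actin cytoskeleton genes had 4 higher and 22 lower of 55 (median log2 change -0.05, camera adjusted p = 0.0352, and adjusted p = 0.209 with an estimated correlation). Their median was -0.022 without MiaPaCa2 wild-type replicate 1 and -0.083 without knockout replicate 1. They did not pass without the first 90 Mb of chromosome 2 or without chromosomes 2 and 7. Nor did they with a filter of 5 FPKM, quantile normalization, array weights, the GC and length correction or genes above 0 in all 12 libraries. The smooth-muscle actin ACTG2, on the short arm of chromosome 2, stood at -1.30. Neuronal markers had 1 higher and 5 lower of 9 (median log2 change -0.12, camera adjusted p = 0.0381, and adjusted p = 0.338 with an estimated correlation). Without MiaPaCa2 knockout replicate 2 the MYC list, with a median of 0.0085, and the actin and neuronal lists did not pass, nor did the neuronal list without wild-type replicate 1. The neuronal list also did not pass without a filter, with a filter of 5 FPKM, quantile normalization, array weights, the replicate block or the GC and length correction, or without chromosomes 2 and 7. The neuronal genes were led by the neuronal tubulin TUBB3 at -1.21 and the synaptotagmin SYT1 at -0.57. In Panc1 they had 2 and 4 (median -0.02, camera adjusted p = 0.672).

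Several lists that passed in Panc1 did not in MiaPaCa2. Focal adhesion genes had 4 higher and 12 lower there (median -0.06, camera adjusted p = 0.147), where the integrin gene ITGAV rose by 0.73 and ITGA3 fell by 0.54. Matrix genes had 6 higher and 6 lower (median 0.00, camera adjusted p = 0.800), where the hemidesmosome collagen COL17A1 fell by 0.88 and the membrane protease MMP14 rose by 0.65. AP-1 genes had 3 higher and 7 lower (median -0.17, camera adjusted p = 0.206), though the matricellular CCN1 rose by 0.98. They passed downward without wild-type replicate 1 (median -0.21). YAP and TAZ targets had 8 and 6 (median 0.00, camera adjusted p = 0.800) and TGF-beta targets 3 and 7 (median -0.02, camera adjusted p = 0.410). The matrix gene TGFBI rose by 0.86 and ID2 fell by 0.94. Adjusted over the list alone, 27 interferon, 7 antigen presentation, 6 Arf pathway, 11 MAPK, 8 AP-1, 7 hypoxia, 5 oxidative phosphorylation, 7 YAP, 11 MYC, 9 endocytosis and 1 Wnt genes were lower in MiaPaCa2. In the same way 39 ribosomal, 23 stress response, 23 autophagy, 5 focal adhesion, 3 cholesterol, 5 TGF-beta and 6 NRF2 genes were higher, the other counts being the same as over all genes.

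Lists that passed camera in neither line still held genes that changed. Arf pathway genes had 5 higher and 17 lower of 37 in Panc1 (median -0.10, adjusted p = 0.447) and 13 and 5 in MiaPaCa2 (median 0.07, adjusted p = 0.219). Within it ASAP1, the closest paralog of ASAP2, fell from 20.9 ± 1.53 to 17.2 ± 0.407 FPKM in MiaPaCa2 (adjusted p = 0.00209). It read 41.9 ± 0.491 and 37.3 ± 1.38 FPKM in Panc1, a log2 change of -0.16 beside an all-gene median of -0.10. ASAP3 rose by 0.81 in Panc1 and the Arf activator CYTH4 fell by 0.995. Epithelial markers had 9 higher and 11 lower of 27 in Panc1 (median -0.04, adjusted p = 0.298) and 2 and 5 in MiaPaCa2 (median 0.04, adjusted p = 0.484). The lipoprotein receptor LSR and the junction protein F11R rose with DSP in Panc1, by 1.49 and 1.10, and in MiaPaCa2 the keratin KRT19 fell by 1.57. Mesenchymal markers had 10 higher and 9 lower of 22 in Panc1 (median -0.01, adjusted p = 0.151) and 4 and 4 in MiaPaCa2 (median 0.00, adjusted p = 0.847). Calponin (CNN1) and MYL9 rose by 2.34 and 1.99 in Panc1, while the calcium-binding S100A4 fell by 1.49 there and rose by 0.54 in MiaPaCa2. ERBB receptors and ligands had 5 higher and 7 lower of 15 in Panc1 (median -0.05, adjusted p = 0.942) and 5 and 2 in MiaPaCa2 (median 0.02, adjusted p = 0.298). The ligand EREG fell by 1.15 in Panc1, and the receptor EGFR rose by 0.42 in MiaPaCa2. MAPK output genes had 14 higher and 12 lower of 34 in Panc1 (median -0.04, adjusted p = 0.583) and 7 and 9 in MiaPaCa2 (median -0.05, adjusted p = 0.410). NF-kB genes had 13 higher and 7 lower of 27 in Panc1 (median 0.12, adjusted p = 0.0672) and 12 and 5 in MiaPaCa2 (median 0.15, adjusted p = 0.0600). They passed in Panc1 without a filter, on the TPM scale and over genes above 0 in all 12 libraries. In MiaPaCa2 they passed with a pseudocount of 0.1 and without wild-type replicate 1 or knockout replicate 1 or 3. Beside CCL2, the interleukin IL32 rose by 1.16 in Panc1, and in MiaPaCa2 the chemokine CCL5 fell by 2.18 and the growth factor gene CSF3 rose from 0.320 ± 0.0736 to 2.17 ± 0.589 FPKM.

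The metabolic and housekeeping lists passed camera in neither line either, apart from the settings named, while several passed with fry. Hypoxia and glycolysis genes had 12 higher and 9 lower of 37 in Panc1 (median -0.01, adjusted p = 0.183) and 13 and 6 in MiaPaCa2 (median 0.05, adjusted p = 0.382). The glucose transporter SLC2A3 and the angiogenic factor VEGFA rose by 1.20 and 0.93 in MiaPaCa2. Cholesterol and fatty acid synthesis genes had 11 higher and 11 lower of 35 in Panc1 (median -0.02, adjusted p = 0.560) and 5 and 4 in MiaPaCa2 (median 0.10, adjusted p = 0.579). In MiaPaCa2 they passed without wild-type replicate 1. Oxidative phosphorylation genes had 6 higher and 25 lower of 49 in Panc1 (median -0.16, adjusted p = 0.219) and 13 and 4 in MiaPaCa2 (median 0.02, adjusted p = 0.620). They passed with quantile normalization, downward in Panc1 and upward in MiaPaCa2, and without a filter in Panc1. Wnt targets had 6 higher and 6 lower of 15 in Panc1 (median -0.02, adjusted p = 0.470) and 2 and 2 in MiaPaCa2 (median 0.04, adjusted p = 0.800). The R-spondin receptor LGR4 fell by 1.79 in Panc1. Heat shock chaperones had 2 higher and 17 lower of 28 in Panc1 (median -0.25, adjusted p = 0.0600) and 6 and 4 in MiaPaCa2 (median 0.03, adjusted p = 0.470). In Panc1 they passed without a filter, on the TPM scale, with quantile normalization, with each line fitted alone, without chromosomes 2 and 7, and without replicate 3 of either knockout. NRF2 targets had 7 higher and 17 lower of 34 in Panc1 (median -0.17, adjusted p = 0.620) and 5 and 9 in MiaPaCa2 (median -0.06, adjusted p = 0.493). The cystine transporter SLC7A11 rose by 0.85 in Panc1. Endocytosis genes had 7 higher and 22 lower of 47 in Panc1 (median -0.09, adjusted p = 0.800) and 10 and 8 in MiaPaCa2 (median 0.04, adjusted p = 0.800). Classical subtype markers had 0 higher and 3 lower of 5 in Panc1 (median -0.23, adjusted p = 0.30) and 1 and 0 in MiaPaCa2 (median -0.02, adjusted p = 0.779). Basal-like markers had 1 higher and 2 lower of 9 in Panc1 (median -0.07, adjusted p = 0.800) and 3 and 3 in MiaPaCa2 (median -0.11, adjusted p = 0.536). Fibroblast markers had 3 higher and 1 lower of 5 in Panc1 (median 0.92, adjusted p = 0.115) and 1 and 0 in MiaPaCa2 (median 0.00, adjusted p = 0.620). Their summed level was 128.1 ± 1.76 and 372 ± 47.6 FPKM in wild-type and knockout Panc1, set by COL1A1. Too few members were tested for a list test of leukocyte markers (of 4, 1 rose and 0 fell in Panc1, and 2 rose and 2 fell in MiaPaCa2), endothelial markers (of 3, 2 rose in Panc1, and 1 rose and 1 fell in MiaPaCa2) and acinar or islet markers (0 of 2 changed in either line). No mitochondrially encoded gene could be matched by the names searched, which start with MT. The symbol RNR2, too ambiguous to assign, had the highest value in the MiaPaCa2 knockout libraries (5944.7, 5967.5 and 5494.8 FPKM), where ACTB had it in the wild-type libraries. The median, the mean and the test did not share a sign for epithelial, EMT, p53, hypoxia, neuronal, ERBB, MAPK, cholesterol, Wnt and NF-kB lists in Panc1 and for matrix, epithelial, EMT, NRF2 and classical lists in MiaPaCa2, and of these none passed.

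Stress response, ribosomal protein, E2F and mitosis lists passed camera in the same direction in both lines, and actin cytoskeleton genes in opposite directions, though the actin calls were lost in several settings in each line. None of these passed in either line with an estimated correlation. Shared changes of single genes were ranked where the mean reached 5 FPKM in the higher group of each line. That leaves out LAPTM5, which rose in both lines, by 1.39 to 1.55 in Panc1 with single libraries left out. Among the genes kept, the largest shared changes were the following. DDIT4, an inhibitor of mTOR signalling, rose from 18.3 ± 0.512 to 64.0 ± 8.48 FPKM in Panc1 and from 25.9 ± 6.14 to 62.5 ± 12.6 FPKM in MiaPaCa2 (adjusted p = 1.2e-06 and 9.0e-05). CHAC1 rose in both. The tetraspanin CD82 (log2 change 1.06 in Panc1 and 1.58 in MiaPaCa2) and the matricellular CCN1 (log2 change 0.88 in Panc1 and 0.98 in MiaPaCa2) rose as well. The histone genes HIST1H1C (log2 change 1.16 in Panc1 and 1.37 in MiaPaCa2) and HIST2H2BE (log2 change 0.87 in Panc1 and 1.08 in MiaPaCa2) read higher, with copies that make their levels uncertain. KRT19, a keratin of ductal epithelium, fell from 541 ± 2.11 to 254 ± 24.0 FPKM in Panc1 and from 105 ± 3.09 to 35.0 ± 3.79 FPKM in MiaPaCa2. The mitotic regulator SAPCD2 (log2 change -0.89 in Panc1 and -0.83 in MiaPaCa2) and the kinase inhibitor CDKN2C (log2 change -0.71 in Panc1 and -0.78 in MiaPaCa2) fell in both. RRM2, the calcium sensor HPCAL1 and the mitochondrial carrier SFXN5 fell in both and lie on the short arm of chromosome 2.

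Genes that went in opposite directions belonged to several pathways. UBE2L6, the enzyme that conjugates ISG15, rose from 2.01 ± 0.490 to 9.91 ± 0.194 FPKM in Panc1 and fell from 11.8 ± 0.708 to 6.79 ± 1.26 FPKM in MiaPaCa2. The interferon-induced IFI6 (log2 change 0.89 in Panc1 and -1.52 in MiaPaCa2) did likewise. The noncoding RNA LOC100507412 (log2 change 0.86 in Panc1 and -2.26 in MiaPaCa2) and the semaphorin SEMA6B (log2 change 1.49 in Panc1 and -0.83 in MiaPaCa2) also rose in Panc1 and fell in MiaPaCa2, while the adenylate kinase AK5 (log2 change -1.72 in Panc1 and 0.76 in MiaPaCa2) went the other way. PMAIP1, the cell-death gene NOXA, rose by 0.34 in Panc1 and fell by 2.37 in MiaPaCa2, with the Panc1 change between 0.17 and 0.49 when single libraries were left out and its call lost without Panc1 wild-type replicate 1 or 3 or knockout replicate 1 and in some other settings.

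The question of whether ASAP2 loss acts alike in the lines was put to all 13340 genes. Calls in the same direction were 667 higher and 846 lower in both lines, where independent calls would give 518 and 905. Another 1349 went in opposite directions, where they would give 1462. With array weights 1319 were lower in both lines and 2193 had opposite calls. Across genes, which are not independent replicates, the log2 changes correlated at r = 0.061 (Spearman's rho 0.058), and at 0.030 without MiaPaCa2 wild-type replicate 3 and 0.036 without knockout replicate 3. The change differed between lines for 7661 genes, 2668 with a higher and 4993 with a lower value in Panc1 (limma, Benjamini-Hochberg), while the median difference of all genes was -0.12. Of the gene lists, interferon genes differed most, with a median difference of 1.56 (camera adjusted p = 5.5e-16, and adjusted p = 0.0204 with an estimated correlation). Focal adhesion genes (0.26, adjusted p = 5.9e-04, and adjusted p = 0.0252 with an estimated correlation) and actin genes (0.13, adjusted p = 0.00425, and adjusted p = 0.0363 with an estimated correlation) were the other lists that passed with an estimated correlation, and all of these had higher changes in Panc1. Ribosomal protein genes (0.24, adjusted p = 9.2e-09), stress response genes (0.22, 0.00410), AP-1 genes (0.36, 0.00167), antigen presentation genes (0.37, 0.00491), matrix genes (0.12, 0.00586) and TGF-beta targets (0.08, 0.0136) also had higher changes in Panc1. Mitosis genes (-0.44, 0.00410) and heat shock chaperones (-0.31, 0.0471) had lower ones. With an estimated correlation these 8 did not pass: adjusted p = 0.477 for ribosomal, stress response, mitosis and heat shock genes, 0.310 for AP-1 and TGF-beta genes, 0.279 for antigen presentation and 0.241 for matrix genes. For E2F, p53, MYC, autophagy, YAP and neuronal lists, some of which passed in 1 line alone, the difference between lines did not pass (adjusted p = 0.814, 0.559, 0.953, 0.814, 0.246 and 0.0721).

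The wild-type lines themselves were compared to give the background on which the knockouts act. Panc1 held AGR2 at 362 ± 9.57 against 0.358 ± 0.620 FPKM in MiaPaCa2 (log2 difference 8.15, adjusted p = 6.4e-13), the myosin phosphatase inhibitor PPP1R14A at 474 ± 30.6 against 0.454 ± 0.728 FPKM, and the surface peptidase ANPEP at 290.1 ± 11.6 against 0.169 ± 0.293 FPKM. It held the immune ligand CD70 at 284 ± 2.47 against 0.257 ± 0.403 FPKM and the lactate dehydrogenase LDHB at 236 ± 15.5 against 0.205 ± 0.354 FPKM. CD24, a surface glycoprotein, read 401 ± 11.5 against 0.520 ± 0.358 FPKM, with copies that make it uncertain. MiaPaCa2 held more of ALDH1A1, an aldehyde dehydrogenase used as a stem-cell marker, with log2 difference -7.06 (0.778 ± 1.26 against 203 ± 17.1 FPKM). It also held more of the noncoding RNA UCA1 (-6.90), the calcium buffer CALB2 (-6.44), LINC02154 (-6.40), the collagen COL1A2 (-6.33) and the G-protein regulator RGS4 (-6.20). Wild-type ASAP2 was 36.9 ± 2.04 FPKM in Panc1 and 13.5 ± 0.32 FPKM in MiaPaCa2. In total 3322 genes differed at least 2-fold with a limma adjusted p below 0.05, 1960 higher in Panc1 and 1362 higher in MiaPaCa2. Replicate 1 of the Panc1 wild-type cells read the 34 genes typical of MiaPaCa2 at a median of 1.59% of their MiaPaCa2 level, where the other wild-type replicates read 0.234% and 0.293%. Knockout replicate 3 read them at 0.705%, and the other knockout replicates at 0.23% and 0.241%, so low Panc1 means of such genes partly rest on single libraries. Replicate 1 of the MiaPaCa2 wild-type cells read 88 genes typical of Panc1 at a median of 0.289% of their Panc1 level, where the others read 0.0214% and 0.0752%.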

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

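The tests of GC content, scaling, copy number, marker levels and culture state in this part were chosen only after the results they address had been seen, while the splits of the libraries were planned.

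Genes on the short arm of chromosome 2, where ASAP2 lies, were lower in the knockout libraries of both lines, over the first 25 Mb in Panc1 and the first 85 Mb in MiaPaCa2. In MiaPaCa2 the whole chromosome stood at -0.21, so the long arm was lower too, by less. GC content is argued against as the whole cause, because the median relative to other genes was -0.57 in Panc1 and -0.38 in MiaPaCa2 after a GC and length correction. A lower DNA copy number of the segment in the knockout cells, such as a difference between clones, is not decided. A loss confined to 1 side of ASAP2 is argued against, because windows on both sides of it were low. After the GC and length correction, those from 0 to 5 Mb and from 10 to 15 Mb stood at -0.669 and -0.735 in Panc1. In MiaPaCa2 they stood at -0.442 and -0.332. With the genes in tertiles of expression, the lowest share below the rest was 94.1% in Panc1 and 91.6% in MiaPaCa2, but the stretches were bounded for being low, so these shares could not have come out low. Whether the fall of ASAP2 mRNA in Panc1 partly belongs to the same shift is open too. DNA was not measured, and wild-type libraries from a parent population with its own copy numbers are not excluded.

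In Panc1 more genes were called lower than higher, 5556 against 2910. After a GC and length correction 51.8% of the called genes were lower and after rescaling by the median ratio 47.2%. Both settings centre the changes, so this balance was fixed by them and decides nothing about GC content or scaling of the libraries as the cause. A general loss of mRNA, GC content and scaling cannot be told apart here. GC content correlated across genes with the change in Panc1 (Spearman's rho 0.407), and the genes of lowest GC content changed by a median of -0.38. The fall of mitosis genes in Panc1 is not explained by GC content alone, since its median was -0.44 after the correction. Whether the GC trend arose in the laboratory or in the cells stays open.

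Interferon genes fell in MiaPaCa2 knockout cells and not as a list in Panc1. GC content is argued against, with a median of -1.30 after the correction. Leukocytes in the wild-type cultures are not decided. The summed leukocyte markers changed by 99.3 FPKM upward in knockout libraries, but the sum follows single genes: LYZ and LAPTM5 rose, while CD68 and CORO1A fell by 0.49 and 0.44. The wild-type level of the list in MiaPaCa2 was high (median log2(FPKM + 1) 2.885), so an interferon-stimulated state of the wild-type culture, a difference between clones and an effect of ASAP2 loss cannot be told apart with 1 set of cultures per genotype. The call for a lower list in MiaPaCa2 may therefore belong to the cultures rather than to ASAP2.

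The knockout effect differed between the lines by limma's test of the difference for 7661 genes. The log2 change in Panc1 minus that in MiaPaCa2 was -1.23 for ASAP2. Among genes that rose most in Panc1 it was 2.88 for FHL1, 3.61 for COL5A1, 2.87 for TUBB2B, 3.05 for SERINC2, 2.75 for DSP, 1.67 for CHAC1, 2.44 for LOC101448202 and 2.36 for ST3GAL5. Among those that fell most in Panc1 it was -2.98 for CCL2, -2.48 for IGFBP3, -2.27 for TBX2, -2.07 for AGR2, -2.25 for PDGFRA, -2.24 for CES1, -2.90 for LIPG and -2.12 for RFLNA. CCL2 and IGFBP3 are listed at 0 or absent in MiaPaCa2, so their difference is that of Panc1 alone. For genes that rose most in MiaPaCa2 it was -2.75 for PRUNE2, -1.09 for LAPTM5, -2.73 for PCDH1, -2.73 for LINC01444, -2.41 for AKR1C1, -2.31 for LYZ, -3.19 for STS and -1.84 for POPDC3. For those that fell most in MiaPaCa2 it was 3.23 for ECSCR, 3.06 for OASL, 3.12 for ISG15, 2.86 for RARRES3, 2.65 for PTX3, 2.81 for IFIT3, 2.01 for IFIT1 and 2.86 for IFIH1. CD82 and KRT19 changed the same way in both lines and differed in size, by -0.53 and 0.48. Genes with opposite calls differed by 3.13 (LOC100507412), 2.72 (PMAIP1), 2.60 (UBE2L6), -2.49 (AK5), 2.41 (IFI6) and 2.32 (SEMA6B).

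Gene lists differed between the lines by a median log2 difference of 1.562 for interferon, 0.368 for antigen presentation, 0.365 for AP-1, 0.264 for focal adhesion, 0.236 for ribosomal protein, 0.217 for stress response, 0.128 for actin, 0.119 for matrix and 0.083 for TGF-beta genes, and of -0.444 for mitosis and -0.315 for heat shock genes. The all-gene median of the difference was -0.12.

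Within a line, 3 libraries against 3 have 10 splits, too few for a share under 0.05. In Panc1 the real split gave 8466 changed genes where the highest other gave 0, 364 genes with a 2-fold change against 0, and 11 gene lists against 11, with 1, 1 and 2 splits as large as the real one. In MiaPaCa2 it gave 4545 genes against 0, 99 against 0, and 10 lists against 10, with 1, 1 and 3 splits as large. The count of lists therefore has little bearing on the genotype. For the wild-type lines it gave 3322 genes against 0, with 1 split as large.

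Splits within both lines at once were drawn 100 times. For the 7661 genes that differed between lines, only the real split was as large (highest other 7544, 1 split as large). The highest other is that of a split that exchanges wild-type and knockout within 1 line, so this split carries the real effects as well. Splits that mix wild-type and knockout within a line remove the effect of that line, so the real split was bound to rank high. The splits therefore do not decide whether the effects differ between the lines by more than chance. For the 667 genes higher in both lines (highest other 543, 1 split as large), the 846 lower in both (806, 1) and the 1349 with opposite calls (1513, 2), the splits decide nothing. Of the other splits only that exchange gave any such genes, since a call in both lines needs called genes in each. Independent calls would give 518 genes higher and 905 lower in both lines, so 1 count lies above and 1 below them. For the correlation of the effects across genes, 0.061, chance is not excluded, because 58 splits gave a size as large and the highest was 0.230.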

How the results depend on the processing

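The GC and length correction and the fits without parts of chromosomes 2 and 7 were chosen after the data were seen; the other alternatives were planned. The counts of genes called higher and lower in each line, of genes that differ between the lines and of genes that differ between the wild-type lines stayed within 1.5 times in all alternatives that recompute them, and so did the correlation of the effects in its sign. Of 250 results for single genes named by the rule, 234 kept their direction and their side of the threshold in each alternative that gave them a value, and none reversed. Those that changed side included ABCC2, ASAP2, ATP5F1D, CALD1, COX6C, GADD45B, HSP90AA1, ORC1, ROBO4, TCF7L2, TP63 and TUBB4A in MiaPaCa2 and PDX1, PMAIP1 and SCD in Panc1. For the changes below, the cause was not tested unless fewer genes or libraries make it plain. Depth is unknown, so precision is known from the spread of 3 libraries alone, and a low gene near 0 FPKM cannot be told from an absent one. A count test could not be run, and the alternative for duplicate symbols had nothing to change.

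With a pseudocount of 0.1 the genes with a 2-fold change numbered 377 higher and 403 lower in Panc1 and 131 higher and 100 lower in MiaPaCa2, and the interferon list in Panc1 (median 0.12) and the NF-kB list in MiaPaCa2 (0.34) now passed. With a filter of 5 FPKM, which tests fewer genes, the 2-fold counts were 126 higher in Panc1 and 30 higher and 29 lower in MiaPaCa2. Lists that no longer passed with it were antigen presentation (0.014) and YAP (0.083) in Panc1 and MYC (-0.065), actin (-0.083) and neuronal (-0.079) in MiaPaCa2, which left 3 lower lists there. Without a filter, 5 lists were higher and 5 lower in Panc1. Matrix (0.0081), AP-1 (0.15), YAP (0.083), TGF-beta (0.0043) and actin (0.11) in Panc1 and neuronal (0) in MiaPaCa2 no longer passed without it, and NF-kB (0.028), oxidative phosphorylation (-0.16), MYC (-0.21) and heat shock (-0.23) in Panc1 now did. Over genes listed above 0 in all 12 libraries, NF-kB in Panc1 (0.14) now passed and actin in MiaPaCa2 (-0.079) no longer did.

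Scaling changed some lists and counts. On the TPM scale interferon (0.038), NF-kB (0.063) and heat shock (-0.31) in Panc1 now passed. With median-ratio scaling 103 genes were lower 2-fold in Panc1. With quantile normalization 5 lists were higher and 4 lower in Panc1 and 3 lower in MiaPaCa2. Matrix (0.067), antigen presentation (0.21), YAP (0.24) and actin (0.033) in Panc1 and MYC (-0.011), actin (-0.035) and neuronal (-0.057) in MiaPaCa2 no longer passed with it, and oxidative phosphorylation (-0.17) and heat shock (-0.23) in Panc1 and oxidative phosphorylation (0.095) in MiaPaCa2 now did. With the GC and length correction 102 genes were lower 2-fold in Panc1 and ASAP2 in MiaPaCa2 passed at -0.18. Matrix (0.043), TGF-beta (0.28) and actin (0.15) in Panc1 and actin (-0.071) and neuronal (-0.058) in MiaPaCa2 no longer passed with it.

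With array weights 1319 genes were lower in both lines and 2193 had opposite calls, ASAP2 in MiaPaCa2 passed at -0.17, and 3 lists were lower in MiaPaCa2, since MYC (-0.041), actin (-0.0054) and neuronal (-0.11) no longer passed. With each line fitted alone, heat shock (-0.25) and autophagy (0.091) in Panc1 now passed. Without the first 90 Mb of chromosome 2, YAP in Panc1 (0.083) and MYC (-0.057) and actin (-0.032) in MiaPaCa2 no longer passed. Without chromosomes 2 and 7, heat shock in Panc1 (-0.25) now passed, and MYC (-0.052), actin (-0.041) and neuronal (-0.12) in MiaPaCa2 no longer did, which left 3 lower lists there.

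The libraries of a line share only a replicate number. Deviations of libraries with the same number correlated across genes at 0.017, 0.034 and 0.078 in Panc1 and at -0.127, -0.165 and -0.002 in MiaPaCa2, and not every library correlated best with its own number. With the replicate block 2771 genes were higher and 5370 lower in Panc1 and 2034 higher and 1925 lower in MiaPaCa2, YAP in Panc1 (0.13) and neuronal in MiaPaCa2 (-0.12) no longer passed, and no other list, count or named gene changed its call.

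With camera and an estimated correlation, 0 lists were higher and 0 lower in Panc1, and 0 were higher and 1 lower in MiaPaCa2. Those that no longer passed were focal adhesion (0.21), matrix (0.040), AP-1 (0.26), E2F (-0.36), mitosis (-0.61), antigen presentation (0.085), stress response (0.61), YAP (0.13), TGF-beta (0.11), ribosomal protein (0.36) and actin (0.074) in Panc1, and E2F (-0.28), mitosis (-0.20), p53 (0.21), stress response (0.24), MYC (-0.065), ribosomal protein (0.15), autophagy (0.18), actin (-0.050) and neuronal (-0.12) in MiaPaCa2. With fry, which asks whether the members move 1 way and compares them with no other genes, 15 lists were higher and 12 lower in Panc1 and 8 and 10 in MiaPaCa2. It also passed Arf pathway (-0.095), epithelial (-0.036), EMT (-0.0074), interferon (0.066), NF-kB (0.12), oxidative phosphorylation (-0.16), MYC (-0.21), heat shock (-0.25), NRF2 (-0.17), endocytosis (-0.091), classical (-0.23), basal-like (-0.074), neuronal (-0.022) and fibroblast (0.92) lists in Panc1. Of these the epithelial, EMT and neuronal lists passed upward, against the sign of their medians. In MiaPaCa2 it also passed Arf pathway (0.072), focal adhesion (-0.055), epithelial (0.037), ERBB (0.016), antigen presentation (-0.083), NF-kB (0.15), hypoxia (0.046) and basal-like (-0.11) lists. There the epithelial list passed downward, against the sign of its median. ERBB (-0.053) and MAPK (-0.036) in Panc1 passed downward with fry, the opposite of their direction with camera.

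With single libraries left out, ASAP2 in MiaPaCa2 ran from -0.20 to -0.067 and passed at -0.20 without knockout replicate 2. Without that library 3 lists were lower in MiaPaCa2, against up to 6 without others, as MYC (-0.10 to 0.01, with 0.0085 there), actin (-0.083 to -0.022) and neuronal (-0.14 to -0.11) no longer passed; neuronal also failed without MiaPaCa2 wild-type replicate 1. Without this replicate AP-1 (-0.21 to -0.11) and cholesterol (0.021 to 0.16) in MiaPaCa2 and autophagy in Panc1 (0.08 to 0.12) now passed, and so did NF-kB in MiaPaCa2 (0.11 to 0.15), as it did without knockout replicates 1 or 3. E2F in MiaPaCa2 (-0.33 to -0.18) and matrix (0.026 to 0.054) and TGF-beta (0.067 to 0.12) in Panc1 kept their calls. YAP in Panc1 (0.086 to 0.18) no longer passed without Panc1 knockout replicate 1, interferon in Panc1 (0.015 to 0.067) now passed without MiaPaCa2 knockout replicate 1, and heat shock in Panc1 (-0.26 to -0.22) without replicate 3 of either knockout.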

Other observations

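The tests in this part were chosen only after the values had been seen.

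Cytosolic aminoacyl-tRNA synthetases, many of them ATF4 targets, went with the stress response genes in Panc1. Of 18 tested, 12 were higher and 3 lower in knockout libraries (median log2 change 0.45, camera p = 6.7e-06, and p = 0.0456 with an estimated correlation). The group was made after the values were seen and its p-values are not adjusted, unlike those of the fixed lists, so they are no independent evidence. AARS read 59.7 FPKM in wild-type and 124.6 FPKM in knockout Panc1 cells and SARS 56.7 and 114.8 FPKM, while DARS, HARS and RARS were lower. In MiaPaCa2 4 were higher and 3 lower (median 0.05, camera p = 0.766, and p = 0.880 with an estimated correlation), and WARS, which interferon also induces, read 255 FPKM in wild-type and 132.4 FPKM in knockout cells.

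Among histone genes, a group made after some of them were seen among the largest shared changes, more were higher than lower in each line, though many were not called. In Panc1 13 of 30 were higher and 2 lower (median 0.30, camera p = 2.2e-04, and p = 0.140 with an estimated correlation), and in MiaPaCa2 14 were higher and 1 lower (median 0.35, camera p = 7.8e-05, and p = 0.118 with an estimated correlation). The genes that prompted the group, HIST1H1C and HIST2H2BE, are among the 30 and the p-values are not adjusted, so they are no independent evidence. HIST1H2BK read 71.1 and 111.2 FPKM in wild-type and knockout Panc1 and 63.9 and 141.4 FPKM in MiaPaCa2, and HIST1H4H rose by 1.59 in MiaPaCa2. Histone genes have near-identical copies, so the levels of single genes are uncertain. The HIST1 genes lie on chromosome 6, which read higher in the Panc1 knockout libraries, with a median of 0.173 relative to the other genes.

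Replicate 1 of the wild-type Panc1 cells held low levels of genes typical of MiaPaCa2. Of 34 genes with at least 20 FPKM in MiaPaCa2 and near 0 in Panc1, 91.2% were higher in that library than in both other wild-type libraries, and 100% of 9 genes were with the first threshold tried, 50 FPKM. Over the 34 genes the median level was 1.59% of that in MiaPaCa2. Knockout replicate 3 of Panc1 read the 34 genes at 0.705%, where the other knockout replicates read 0.23% and 0.241%. A small share of MiaPaCa2 RNA or reads in wild-type replicate 1 may be the source. Without that library 2655 genes were called higher and 5002 lower in Panc1.

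Other chromosome stretches were lower in knockout libraries than the rest of the genes. In Panc1 chromosome 7 had a median of -0.297 over 477 genes, 81.6% of which lay below the rest, and X had -0.186. Chromosome 6 went the other way in Panc1, with a median of 0.173 over 482 genes, 26.8% of which lay below the rest. In MiaPaCa2 the windows of chromosome 14 from 90 to 110 Mb stood at -0.319 and -0.338 after the GC and length correction.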
